A study of Mus musculus with 14 samples.

How the data were processed

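Gene expression was measured in mSCC-38, a mouse cell line that came from a skin squamous cell carcinoma induced with the carcinogens DMBA and TPA. Per the labels, cells were transfected with 1 of 2 siRNAs against the transcript AK144841 (Si1AK and Si2AK) or with a control siRNA (SiC), using the lipid reagent RNAimax, and were harvested after 72 h, or were left untransfected (NT), with no time given for the latter. There were 4 NT, 3 SiC, 4 Si1AK and 3 Si2AK samples. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Total RNA (0.2 µg, RNA integrity number 9) was amplified and labelled with the dye Cy3 by the Agilent Low RNA Input QuickAmp method, and 600 ng of product was hybridised to a 1-colour Agilent mouse array.

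Per the file headers, images were read with Agilent Feature Extraction 10.7.3.1 and probes were placed on the mouse genome build mm9. Per the file headers, the processed signal is an intensity from which the software subtracted background and spatial trends within each array, without scaling between arrays. Per the file headers, the raw mean and local background intensities and the 0 or 1 marks for spots well above background, saturated, uneven or outlying (a unit other than intensity) were deposited as well. The authors' deposited value table holds log2 values of the same arrays. Per the submitters' processing notes limma was used, with no version given. The table's columns correlated best with log2 of the raw mean signal (Pearson r across spots of at least 0.991, where spots are not independent replicates). All 14 columns had a median over all spots of 6.51 and nearly the same distribution. A log2 scale, higher values for brighter spots and no centring per gene were borne out by this comparison. The background step behind the table stays unknown.

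Each array held 62976 spots, of which 59305 were no controls. Spots marked as uneven or as outliers of their replicate spots were left out and the spots of a probe were averaged, which gave 55681 probes. Log2 of the processed signal was taken minus the 75th percentile of each array, so every level and difference is relative to that percentile. Probes were kept if well above background on every array of at least 1 group (30326 probes). The probe with the highest mean stood for its gene, and 21318 genes were tested, of which 13558 had a gene symbol. Other probes of a gene were used only in the alternative that averaged them. Names came from RefSeq accessions of a mouse GRCm38.p6 gene table for 27656 probes, of which 1711 had another symbol in the array's own annotation. The other probes kept the name the array gives. No coordinates came from that table. No probe was saturated on any array, and 312 genes lacked 319 single values. Some families are nearly identical in sequence, such as the Lce1 genes, and how far their probes bind each other's transcripts is uncertain.

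All 14 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 10 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over all genes. The groups thus shared a common estimate of spread per gene. Where SiC or Si2AK arrays varied more than the others, p-values of their comparisons may be too small. A gene was called at an adjusted p below 0.05. The 4 comparisons were Si1AK with SiC, Si2AK with SiC, SiC with NT and Si2AK with Si1AK. Errors of group means are SD, and errors of differences are the moderated SE of limma. Where all arrays of a group fell short of the well-above-background mark, the change is given as a bound. It was taken from the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal well above background and the probe's own signal. The number of arrays limits the precision of every value.

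Before the data were examined, 24 gene lists were fixed: cornified envelope and terminal keratinocyte differentiation, basal keratinocyte, stressed or wound-activated keratinocyte, stefins and clade B serpins, epithelial junction, mesenchymal transition, TGF-beta and YAP target, matrix protease and invasion, actin cytoskeleton and SRF target, interferon response, inflammatory cytokine and NF-kB target, immediate early and MAPK feedback, p53 target, unfolded protein and integrated stress response, mitosis, DNA replication, cholesterol synthesis, hypoxia and glycolysis, NRF2 and glutathione, Notch pathway, and markers of fibroblasts, leukocytes, endothelium and melanocytes. The sample groups, the tests, the alternatives and the rule for naming genes were fixed then too, except where a choice is said to be later. Lists were tested with camera from limma (preset inter-gene correlation of 0.01, adjusted over the lists). Camera compares a list with the other genes. Splits of the arrays that mixed the groups, given below, passed lists as well, so its p-values with the preset correlation are likely too small. A correlation estimated per list, and the test fry, which asks whether members move on balance to 1 side, were alternatives. Genes were named by rule: the 12 highest and 12 lowest genes called with both siRNAs, by the smaller of the 2 changes; the 6 called genes with the largest rise and fall per comparison; up to 4 called members per list; and up to 3 per direction known only as a bound. Of the genes this rule took, 2 are not reported here.

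The procedure was tested on simulated data with the real means and spread, in which a known set of genes was changed by 1.5-fold, 2-fold or 4-fold. Noise was independent and of equal spread across the arrays of a gene, without correlated arrays or arrays with raised signal. The shares that follow hold for such data and may differ for the real arrays. For Si1AK with SiC, 19.4%, 56.5% and 79.7% of the changed genes of each size were recovered, and 5 of 108 calls were false. For Si2AK with SiC the shares were 22.2%, 61.3% and 83.3% (9 of 125 calls false), for SiC with NT 35.1%, 55.4% and 80.3% (8 of 119 false), and for Si2AK with Si1AK 29.6%, 62.5% and 73.8% (5 of 114 false). Overlap between the comparisons with SiC was set beside 100 simulations in which all arrays, SiC included, were drawn around a common mean per gene. The measured SiC arrays were thus not part of them. Alternatives fixed beforehand were normexp background correction with an offset of 50, quantile normalization, the authors' value table, no filter or a stricter filter on dim probes, the mean of a gene's probes, an intensity trend with a robust prior, only the groups compared in the fit, slide or replicate number as a block, each of the 2 slides alone, NT as the control, and each array left out in turn. The alternatives that left out both arrays with raised signal, or kept bright genes only (mean of at least -2 relative to the 75th percentile), were chosen after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

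The targeted transcript AK144841 was named in 0 cells of the array annotation used here, so its level and the genes within 500 kb of it were not analysed here. Sequences of the siRNAs were not used here.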

Results

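The 14 arrays compared held 1 sample each of mSCC-38 mouse skin carcinoma cells. The comparisons of Si1AK and Si2AK with SiC asked how the transcripts of these cells responded to 2 distinct siRNAs directed at the long non-coding transcript AK144841, and untransfected cells (NT) gave a second baseline. Differences from NT include any effect of transfection, which SiC shares. The groups held 4 NT, 3 SiC, 4 Si1AK and 3 Si2AK arrays, on 2 slides of 7. Slide 1 held only replicate 1 of SiC and slide 2 only replicate 3 of Si2AK. Values of these groups within those slides therefore rest on 1 array. The median processed signal was between 23.5 and 58.7 on 12 arrays, but 270.9 on SiC replicate 1 and 107.5 on Si2AK replicate 2. The share of probes well above background was between 52.7% and 60.1% on those 12 arrays, 90.5% on SiC replicate 1 and 84.9% on Si2AK replicate 2. These arrays lay at -164 and -109 on the first principal component, which held 59.1% of the variance, while the others lay between -42.0 and 44.8. The targeted transcript was not analysed here, so no value checks the knockdown.

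**Figure D1:**
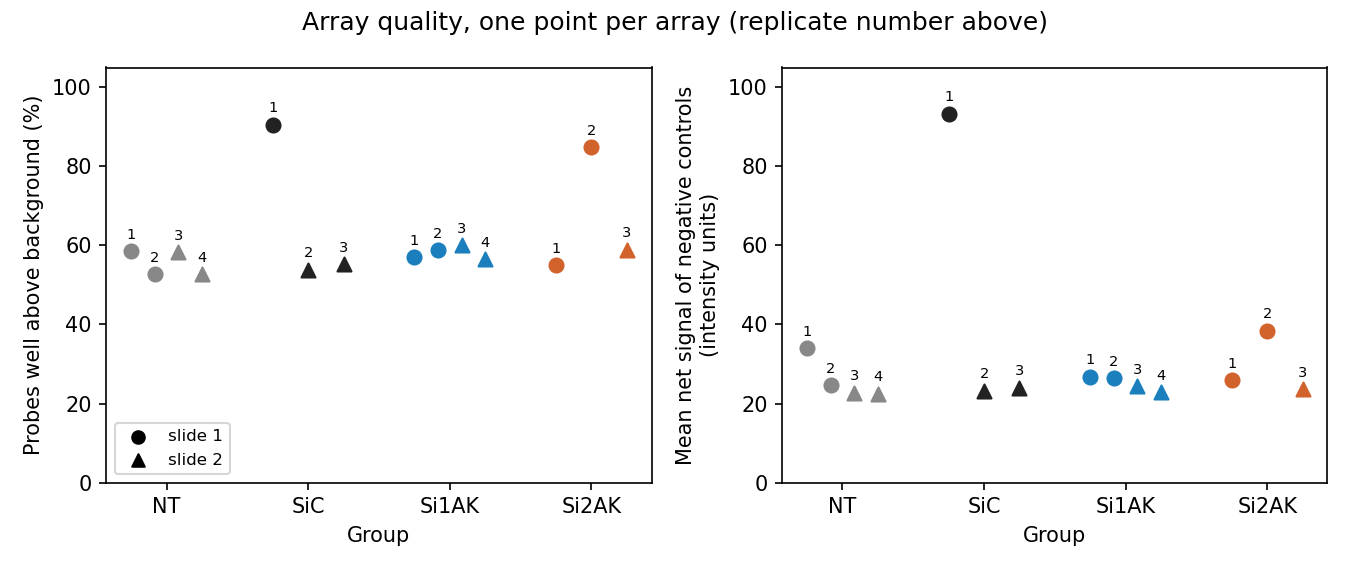
Array quality by group, 1 point per array with its replicate number and with the slide as the symbol. The left axis is the share of probes well above background in percent. The right axis is the mean net signal of negative controls in intensity units. The share of probes well above background was 90.5% on SiC replicate 1 and 84.9% on Si2AK replicate 2, and at most 60.1% on the other arrays.

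Lce1i, Cpa4, Cryab and Csf2 were among the genes that rose most with both siRNAs. The late cornified envelope gene Lce1i, of a family that builds the outer layer of skin, rose by a log2 difference of 2.13 ± 0.156 (SE; limma adjusted p = 7.85e-05) with Si1AK and of 2.38 ± 0.167 (adjusted p = 2.26e-05) with Si2AK against SiC. Its level relative to the 75th percentile was 1.98 ± 0.365 (SD, n = 3) in SiC, 4.11 ± 0.188 (SD, n = 4) in Si1AK and 4.36 ± 0.07 (SD, n = 3) in Si2AK, and its probe lies on chromosome 3, 92581159 to 92581218 of mm9. With Si1AK and Si2AK, Lce1g rose by 2.03 and 2.31, Lce1c by 2.00 and 2.10, and Lce1a2 by 1.30 and 1.46. Cryab, a small heat shock protein, rose by 2.05 ± 0.156 and 1.64 ± 0.167, and Cpa4, a carboxypeptidase, by 2.22 ± 0.15 and 1.40 ± 0.161. Csf2, which encodes the cytokine GM-CSF, rose by 1.45 ± 0.224 and 2.49 ± 0.24. Nppb, the precursor of brain natriuretic peptide, rose by 1.90 and 2.17, Sema7a, a membrane-bound semaphorin, by 1.76 and 2.18, and Rgs16, a regulator of G protein signalling, by 1.69 and 1.64. Krtap10-4, a hair keratin associated protein, rose by 1.37 and 1.64.

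Esco2, Clspn and Timeless were among the genes that fell with both. Esco2, an acetyltransferase of sister chromatid cohesion, fell by 1.11 on the log2 scale with Si1AK (SE 0.178, adjusted p = 0.00517) and fell by 1.22 with Si2AK (SE 0.19, adjusted p = 0.00183). For Clspn, an adaptor of the replication checkpoint, the differences were -0.89 and -0.95, for Timeless, its partner at the replication fork, -0.73 and -1.15, and for Fancc, of the Fanconi anaemia repair pathway, -0.85 and -0.68. Some of the largest falls came with high SiC values. Scai, a repressor of invasion, was at -2.46 and -2.08 against SiC, while SiC stood above NT by 2.04 (adjusted p = 0.636) and the differences from NT were -0.42 and -0.037, which did not pass. It was well above background on 1 of 4 Si1AK and 1 of 3 Si2AK arrays, so the sizes of these falls are uncertain. Its call with Si1AK was lost without Si1AK replicate 2 (-2.35), and with Si2AK without Si2AK replicate 1 or SiC replicate 3 (-1.64 or -1.94). Mrgprx2, Lrrc10b and Cdh7 were well above background in SiC and on no array of the other groups, and were at least 11-fold, 11.4-fold and 4.2-fold lower with Si1AK and at least 8.64-fold, 8.96-fold and 3.31-fold lower with Si2AK. For SiC against NT their adjusted p = 0.053, 0.139 and 0.139.

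In total, 347 genes were called with both siRNAs in the same direction, of which 255 rose and 92 fell, and 72 were called in opposite directions. Arrays of all groups, SiC included, were also simulated without group differences, and 100 such simulations gave 0 shared calls with limma. Without differences limma calls few genes at all, so this 0 cannot tell whether the shared calls come from the SiC arrays. Independent sets of these sizes would share 57.8 higher and 12.3 lower genes. The covariance of the log2 differences across genes was 0.129, beside 0.0991 in the simulations, and the correlations were 0.479 and 0.534, where genes are not independent replicates. The simulations gave all arrays the same spread within a gene, so they leave out any wider spread of SiC replicate 1. With no shared arrays, 471 genes were shared between Si1AK against NT and Si2AK against SiC (r = 0.253), and 308 between Si1AK against SiC and Si2AK against NT (r = -0.083). Of the 255 higher genes 182 were also called higher with both siRNAs than in NT, and of the 92 lower genes 59 were also called lower. With slide as a block 536 genes were shared, with only the groups compared in the fit 19, on slide 2 alone 17, and on slide 1 alone 0. There limma gave 8363 genes with Si1AK and 7669 with Si2AK at an unadjusted p under 0.05, and the only SiC array, replicate 1, was assumed to vary like the other groups. Without Si1AK replicate 1 or 2, Si2AK replicate 1 or SiC replicate 2 the count was 153, 156, 197 or 220.

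**Figure D2:**
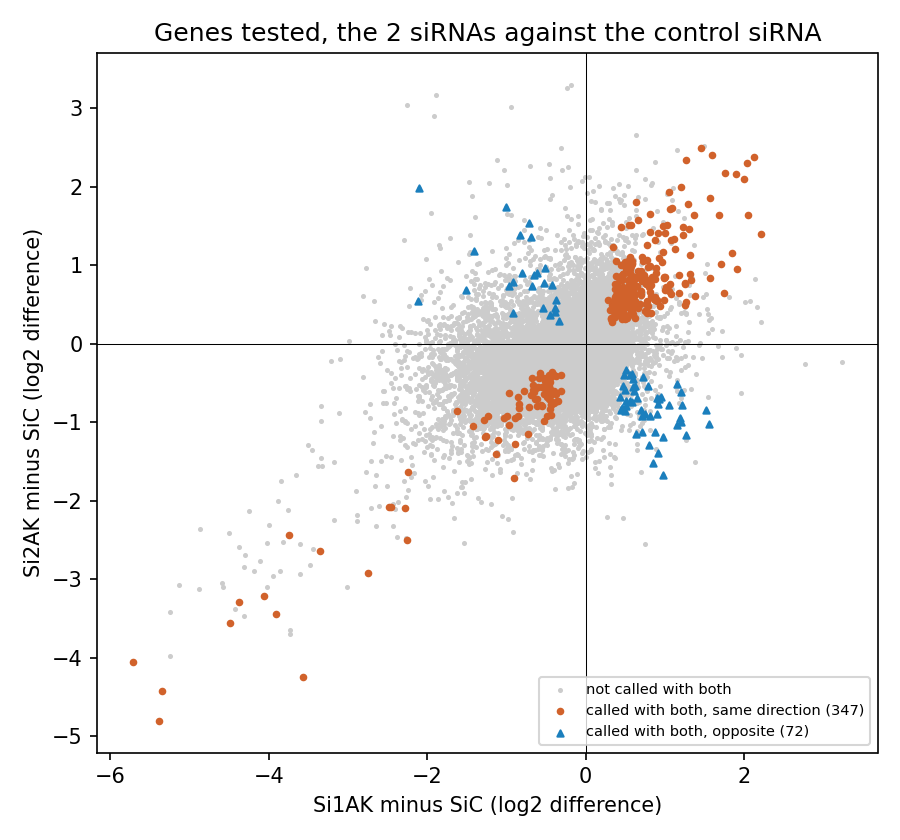
Log2 difference from SiC of each tested gene with Si1AK (x axis) and with Si2AK (y axis); orange points are the 347 genes called with both in the same direction and blue triangles the 72 called in opposite directions. Simulated arrays without group differences and with equal spread, compared with a shared SiC group, gave a correlation of 0.534 between the axes, beside 0.479 measured.

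**Figure D3:**
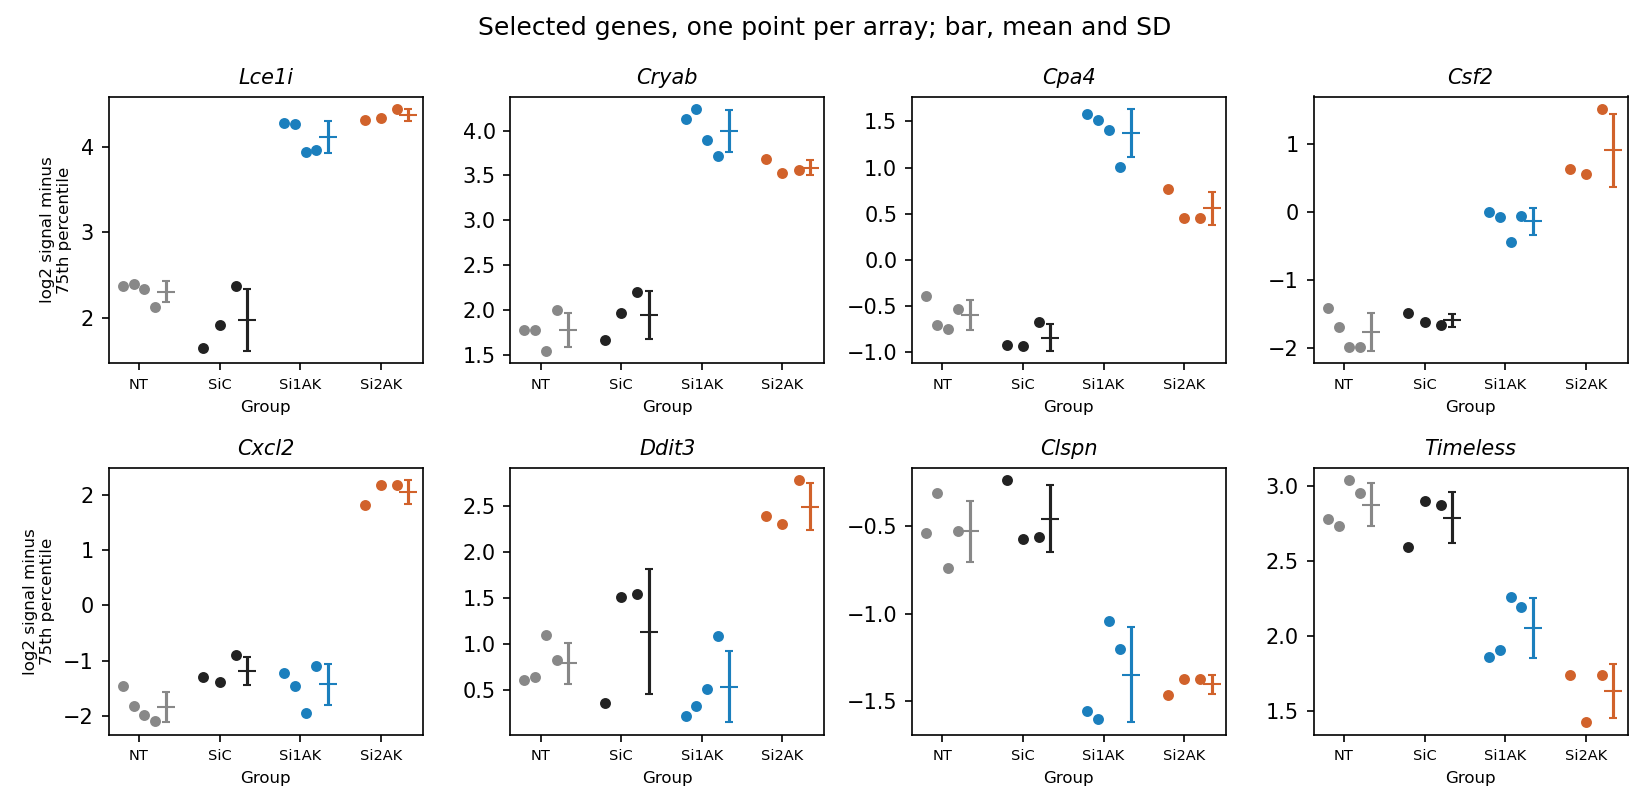
Log2 signal minus the 75th percentile of the array for 8 named genes in the 4 groups, 1 point per array with the group mean and SD. The mean of Lce1i was 1.98 in SiC, 4.11 in Si1AK and 4.36 in Si2AK.

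In Si1AK against SiC the lists of p53 targets, actin genes and matrix proteases passed, with positive medians. Unless stated otherwise, a list passed by camera with its preset correlation, which also passed lists in splits that mixed the groups. Of 32 measured targets of p53, the transcription factor of the DNA damage response, 13 rose, 0 fell and 19 were not called (17 rose and 1 fell adjusted over the list alone). Dcxr, a xylulose reductase, rose by 1.25 ± 0.154 (adjusted p = 0.00118), Btg2, an antiproliferative factor, by 1.08 ± 0.164 (adjusted p = 0.0039), and Tnfrsf10b, a death receptor, by 0.83 ± 0.106 (adjusted p = 0.00142). The list passed camera (median 0.54, adjusted p = 2.37e-14, and adjusted p = 0.0159 with an estimated correlation), with medians of 0.50 with slide as a block, 0.78 on slide 1 and 0.42 on slide 2. Among 22 genes of the actin cytoskeleton, 5 rose and 17 were not called (6 rose adjusted over the list alone). Acta2, smooth muscle actin, rose by 1.07 ± 0.094 and Cnn2, a calponin, by 0.53 ± 0.094 (list median 0.27, adjusted p = 6.71e-08, and adjusted p = 0.0159 with an estimated correlation). Matrix protease genes rose in 5 of 22 cases, with 17 not called (8 rose adjusted over the list alone). Plau, the urokinase activator of plasmin, rose by 1.26 ± 0.13, its receptor Plaur by 0.94 ± 0.112 and the collagenase Mmp1a by 1.16 ± 0.157 (list median 0.41, adjusted p = 1.78e-07, and adjusted p = 0.116 with an estimated correlation). Without SiC replicate 1 the matrix protease median was 0.25. Against NT the p53, actin and matrix protease lists passed with medians of 0.52, 0.17 and 0.29. With an estimated correlation the p53 and actin lists still passed there (camera adjusted p = 0.0248 and 0.0248). The matrix protease list did not (adjusted p = 0.0526). The actin and matrix protease medians were 0.37 and 0.71 on slide 1 and 0.21 and 0.29 on slide 2.

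The DNA replication and mitosis lists had negative medians with Si1AK, and against SiC most of their members were not called. Of 43 DNA replication genes 5 fell, 0 rose and 38 were not called (15 fell adjusted over the list alone), among them Gins1, of the replicative helicase, which fell by 0.55 on the log2 scale (SE 0.086, adjusted p = 0.00479). Of 35 mitosis genes 5 fell and 30 were not called (17 fell adjusted over the list alone), and 35 of the differences were negative. Both lists passed camera (medians -0.27 and -0.32, adjusted p = 2.13e-09 and 1.33e-09), and not with an estimated correlation (adjusted p = 0.201 and 0.147). Their medians were -0.26 and -0.28 with slide as a block, -0.30 and -0.34 on slide 2, and -0.11 and -0.16 on slide 1, where neither passed. Against NT 22 and 17 members fell, with medians of -0.44 and -0.46, and the lists passed, but not with an estimated correlation. Among TGF-beta and YAP targets 5 of 18 rose (6 rose and 1 fell adjusted over the list alone). Ankrd1, a mechanosensitive ankyrin repeat protein, rose by 1.84 ± 0.267, Ccn1, a matricellular protein, by 1.03 ± 0.18, and Thbs1, thrombospondin, by 0.71 ± 0.137 (list adjusted p = 0.00439, and adjusted p = 0.173 with an estimated correlation). This list had a median of 0.14, of 0.14 against NT and of 0.22 without SiC replicate 1, and did not pass under quantile normalization (median 0.22) or in the authors' value table (median 0.21). Immediate early and MAPK feedback genes rose in 5 of 33 cases, Myc, a growth-promoting transcription factor, by 0.51 ± 0.072 among them, and 1 fell (10 rose and 1 fell adjusted over the list alone; list median 0.19, adjusted p = 0.000103, and adjusted p = 0.147 with an estimated correlation). Against NT, 1 of 33 rose and the list did not pass (median 0.060).

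In the keratinocyte lists few members passed with Si1AK. Of 31 cornified envelope genes 3 rose (5 adjusted over the list alone): Lce1c, Casp14, a caspase of keratinocyte differentiation, by 1.90 ± 0.151, and Crct1 by 1.29 ± 0.218 (list adjusted p = 0.00192, and adjusted p = 0.201 with an estimated correlation). Basal keratinocyte genes rose in 3 of 21 cases (4 adjusted over the list alone) and stressed keratinocyte genes in 2 of 19 (4 adjusted over the list alone). The latter were S100a7a, an antimicrobial S100 protein (1.17 ± 0.123), and Plaur (0.94). Both lists passed (adjusted p = 0.00105 and 0.017, and adjusted p = 0.278 and 0.201 with an estimated correlation), but not without SiC replicate 1 (medians 0.11 and 0.25). Against NT the basal list did not pass (median 0.060, 2 genes rising and 2 falling). The cornified envelope, stressed and stefin lists passed there with medians of 0.088, 0.001 and 0.16. With an estimated correlation these 3 calls were lost (camera adjusted p = 0.322, 0.314 and 0.314). The cornified envelope median, 0.20, was 0.12, 0.31 or 0.34 without Si1AK replicate 2, Si1AK replicate 3 or SiC replicate 1, and the stressed median, 0.12, was 0.27 without Si1AK replicate 3. Of 17 stefins and clade B serpins, protease inhibitors, 2 rose and 1 fell (3 and 2 adjusted over the list alone). Serpinb2 rose by 1.08 ± 0.135 and Cst6 by 0.68 ± 0.108, and Serpinb1a was at -1.01 ± 0.199, a call lost without Si1AK replicate 1, SiC replicate 2 or SiC replicate 3 (-0.93, -0.91 or -0.84). This list passed with adjusted p = 0.017, and adjusted p = 0.201 with an estimated correlation. Under quantile normalization the stressed keratinocyte and stefin lists did not pass (medians 0.34 and 0.48), nor did the stefin list with both arrays of raised signal left out (median 0.24). With slide as a block the medians of the cornified envelope, basal, stressed and stefin lists were 0.16, 0.26, 0.14 and 0.27. On slide 1 they were 0.23, 0.50, 0.40 and 0.38, where the cornified envelope and stefin lists did not pass, and on slide 2 0.33, 0.12, 0.035 and 0.17, where the stressed list did not pass.

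Smaller shifts passed in 4 more lists. For the interferon response 2 of 30 members rose (2 adjusted over the list alone), with Oas1a, an RNA sensor, at 1.05 ± 0.112. For mesenchymal transition 1 of 24 rose (3 rose and 1 fell adjusted over the list alone), for NRF2 and glutathione genes 3 of 31 (3 adjusted over the list alone), and in the unfolded protein list 1 of 34 fell (0 adjusted over the list alone). Their medians were 0.075, 0.091, 0.064 and -0.13 (adjusted p = 0.0226, 0.0425, 0.027 and 0.0218), and with an estimated correlation adjusted p = 0.295, 0.147, 0.594 and 0.643. Each of these calls was lost with single arrays left out: without SiC replicate 2 the interferon and unfolded protein medians were 0.025 and -0.069, without SiC replicate 3 -0.006 and -0.084. These lists passed without SiC replicate 1 (medians 0.15 and -0.28), and the interferon list without Si1AK replicates 1 and 2 (medians 0.12 and 0.048). The NRF2 median was -0.063 without SiC replicate 1 and 0.050 without Si1AK replicate 2, where the call was lost, and 0.13 and 0.13 without SiC replicates 2 and 3, where it was kept. The mesenchymal median was 0.10, 0.083, 0.061, 0.18 and 0.086 without Si1AK replicates 1 and 2 and SiC replicates 1, 2 and 3 in turn. The interferon, mesenchymal, NRF2 and unfolded protein medians were 0.050, 0.10, 0.079 and -0.12 with slide as a block, -0.17, 0.30, 0.29 and 0.088 on slide 1, and 0.11, -0.007, -0.081 and -0.21 on slide 2, so each call was lost in 1 or more of these fits. The mesenchymal call was lost with the replicate block too (median 0.078), and against NT the mesenchymal and NRF2 lists did not pass (medians -0.004 and -0.078). Against NT the interferon list passed with 7 members rising and a median of 0.44, also with an estimated correlation. SiC itself stood above NT in this list, with a median of 0.34. The unfolded protein list passed against NT with 4 falling and a median of -0.27, but not with an estimated correlation (camera adjusted p = 0.369). Lists that did not pass were epithelial junction, inflammatory cytokine, cholesterol synthesis, hypoxia and glycolysis, and Notch pathway (adjusted p = 0.496, 0.783, 0.129, 0.986 and 0.279). The cholesterol list (median -0.14) passed with medians of -0.16 with the replicate block, -0.15 under quantile normalization, -0.14 in the authors' value table, -0.13 with bright genes only, -0.14 on slide 2, -0.22 with both arrays of raised signal left out, and -0.22 and -0.17 without SiC replicate 1 and Si1AK replicate 4, so this list stays open. The hypoxia list passed without SiC replicate 1 (median -0.20), the Notch list on slide 2 (0.14) and, with no filter on dim probes, the Notch and junction lists (0.13 and -0.017). Against NT the inflammatory, cholesterol and hypoxia lists passed (medians 0.18, -0.25 and -0.21), but not with an estimated correlation (camera adjusted p = 0.169, 0.309 and 0.617). For SiC against NT the medians of these lists were 0.37, -0.18 and -0.17. In the inflammatory list Csf1, the macrophage growth factor, rose by 0.86 ± 0.118. Markers of fibroblasts, leukocytes, endothelium and melanocytes did not pass either (adjusted p = 0.899, 0.986, 0.986 and 0.986). Camera pointed up for the epithelial junction, hypoxia and melanocyte lists, whose medians were -0.017, -0.031 and -0.34 and means -0.12, -0.020 and -0.070.

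Over all genes, 941 were called between Si1AK and SiC, 678 higher and 263 lower, of which 119 and 88 changed at least 2-fold. Against NT 859 were higher and 648 lower, 178 and 27 of them at least 2-fold, so the balance of rises and falls depended on the control. The median difference of all genes was -0.060, and 0.061 under quantile normalization. The largest changes included Asphd2 (2.22 ± 0.358) and Tor2a, a torsin ATPase that fell by 2.12 on the log2 scale (SE 0.113, adjusted p = 1.09e-05). Serpind1, a thrombin inhibitor, was below the background mark in SiC and at least 1.53-fold higher with Si1AK. With only Si1AK and SiC in the fit, 251 genes were called. With slide as a block 1380 genes and 13 lists were called, on slide 1 alone 0 and 8, and on slide 2 alone 34 and 14 (limma; on slide 1 8363 genes had an unadjusted p under 0.05), beside 15 lists over both slides. Without Si1AK replicate 1, Si1AK replicate 2 or SiC replicate 2 the number of genes was 460, 427 or 627.

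In Si2AK against SiC the inflammatory cytokine, unfolded protein and DNA replication lists passed, and most of their members were called. Of 31 inflammatory cytokine and NF-kB targets, 18 rose, 0 fell and 13 were not called (20 rose adjusted over the list alone). The neutrophil attractant Cxcl2 rose by 3.26 ± 0.232 (limma adjusted p = 2.26e-05), from -1.20 ± 0.257 (SD, n = 3) in SiC to 2.06 ± 0.215 (SD, n = 3) in Si2AK. Ptgs2, the inducible cyclooxygenase, rose by 2.13 ± 0.177 and Csf3, the granulocyte growth factor, by 2.00 ± 0.282. The list had a median of 0.69 (adjusted p = 1.3e-11, and adjusted p = 0.0345 with an estimated correlation), and of 0.69 with slide as a block, 0.67 on slide 1 and 0.92 on slide 2. For Si2AK against SiC, slide 1 had only SiC replicate 1 and slide 2 only Si2AK replicate 3, so each slide has 1 array on 1 side. Of 34 genes of the unfolded protein and integrated stress response, 19 rose and 0 fell (19 rose adjusted over the list alone). Ppp1r15a, which restores translation after stress, rose by 1.82 ± 0.295, Trib3, a pseudokinase, by 1.57 ± 0.289, and Dnajb9, an endoplasmic reticulum chaperone, by 1.45 ± 0.183 (list median 0.57, adjusted p = 4.35e-12, and adjusted p = 0.105 with an estimated correlation). Its median was 0.61 with slide as a block, 0.77 on slide 1 and 0.53 on slide 2. Against NT 24 inflammatory and 17 unfolded protein genes rose, with list medians of 1.25 and 0.47. For SiC against NT the medians of these lists were 0.37 and -0.12.

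DNA replication genes fell in 31 of 43 cases with Si2AK, with 12 not called (37 fell adjusted over the list alone). Mcm10, which acts in activation of the replicative helicase, fell by 0.92 on the log2 scale (SE 0.119, adjusted p = 0.000696), and the polymerase subunit Pola1 and the clamp loader subunit Rfc3 were at -1.08 ± 0.232 and -0.86 ± 0.133. The list median was -0.54 (adjusted p = 7.32e-23, and adjusted p = 0.0416 with an estimated correlation), -0.54 with slide as a block, -0.34 on slide 1 and -0.67 on slide 2. Mitosis genes fell in 11 of 35 cases (17 adjusted over the list alone), with Ttk, a spindle checkpoint kinase, at -0.70 ± 0.146 and Foxm1, a transcription factor of mitotic genes, at -0.58 ± 0.119 (list adjusted p = 6.89e-09, and adjusted p = 0.0924 with an estimated correlation). On slide 1 alone the mitosis list did not pass (median -0.22). Against NT 39 replication and 20 mitosis genes fell, with list medians of -0.68 and -0.49.

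The stressed keratinocyte and stefin lists passed with Si2AK under either correlation. Of 19 stressed keratinocyte genes 11 rose (13 adjusted over the list alone), among them the epidermal growth factor receptor ligands Ereg (1.91 ± 0.177), Hbegf (1.87 ± 0.256) and Areg (1.85 ± 0.278). Of 17 stefins and clade B serpins 10 rose (12 adjusted over the list alone), Serpinb1a by 1.74 ± 0.212 and Stfa2 by 1.48 ± 0.252. These lists had adjusted p = 8.5e-08 and 6.89e-09, and adjusted p = 0.024 and 0.0193 with an estimated correlation, with medians of 0.80 and 0.80 on slide 1 and 0.73 and 0.90 on slide 2. Basal keratinocyte genes rose in 10 of 21 cases (15 rose and 1 fell adjusted over the list alone): Dsg3, a desmosomal cadherin well above background on 2 of 3 SiC arrays, by 3.02 ± 0.528, and Col17a1, a hemidesmosomal collagen, by 1.02 ± 0.142. Of 31 cornified envelope genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), with Sprr2h, a small proline-rich envelope protein, at 2.66 ± 0.341 and Lce3c at 2.31 ± 0.313. In the epithelial junction list 3 of 20 rose (3 adjusted over the list alone), among them the splicing regulator Esrp2 (1.23 ± 0.086). These 3 lists passed (adjusted p = 9.58e-08, 3.28e-06 and 0.0096), and not with an estimated correlation (adjusted p = 0.0924, 0.0764 and 0.0924). Their medians were 0.43, 0.58 and 0.17 with slide as a block, 0.60, 0.37 and 0.30 on slide 1, where the junction list did not pass, and 0.34, 1.05 and 0.11 on slide 2. The cornified envelope median, 0.81, was 0.49, 0.36 or 0.47 without Si2AK replicate 2, SiC replicate 2 or SiC replicate 3, and the junction median, 0.22, was 0.11 without Si2AK replicate 2. Against NT all 5 lists passed, and the stressed, stefin, basal, cornified envelope and junction medians were 0.75, 0.93, 0.22, 0.66 and 0.20. With an estimated correlation the stressed and stefin lists still passed against NT (camera adjusted p = 0.0241 and 0.0193). The basal, cornified envelope and junction lists did not (adjusted p = 0.247, 0.12 and 0.206).

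Lists of signalling and cytoskeletal genes passed as well. Immediate early and MAPK feedback genes rose in 11 of 33 cases and 1 fell (20 rose and 2 fell adjusted over the list alone), Atf3, a stress-induced transcription factor, by 2.21 ± 0.379 and Fos by 1.45 ± 0.212 (list adjusted p = 9.58e-08, and adjusted p = 0.0416 with an estimated correlation). Actin genes rose in 7 of 22 cases (14 adjusted over the list alone), Acta2 by 1.71 ± 0.1 and Cnn1, a smooth muscle calponin, by 1.19 ± 0.177 (list adjusted p = 1.47e-08, and adjusted p = 0.0139 with an estimated correlation). Among p53 targets 10 of 32 rose and 1 fell (12 and 2 adjusted over the list alone), among them the polo-like kinases Plk3 (1.89 ± 0.143) and Plk2 (1.10 ± 0.114). Among matrix proteases 7 of 22 rose (10 rose and 2 fell adjusted over the list alone), with Adamts1 at 1.36 ± 0.209. Hypoxia and glycolysis genes rose in 5 of 34 cases (5 adjusted over the list alone), with the hexokinase Hk2 at 0.75 ± 0.11. These 3 lists passed (adjusted p = 0.00356, 0.00402 and 0.00696, and adjusted p = 0.23, 0.238 and 0.656 with an estimated correlation), but without SiC replicate 1 the matrix protease and hypoxia lists did not (medians 0.25 and 0.013), nor did the hypoxia list without Si2AK replicate 3 (median 0.049) or against NT (-0.041). The hypoxia median, 0.15, was 0.25 or 0.28 without Si2AK replicate 1 or SiC replicate 2, and the p53 median, 0.17, was 0.28 or 0.086 without Si2AK replicate 2 or SiC replicate 1. Against NT the immediate early, actin, p53 and matrix protease lists passed with medians of 0.33, 0.30, 0.17 and 0.18. With an estimated correlation only the actin list did so against NT (camera adjusted p = 0.0193). The adjusted p was 0.175, 0.361 and 0.247 for the immediate early, p53 and matrix protease lists. The medians of the immediate early, actin, p53, matrix protease and hypoxia lists were 0.57, 0.49, 0.34, 0.55 and 0.37 on slide 1 and 0.34, 0.28, 0.25, 0.29 and 0.27 on slide 2.

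Members of other lists went both ways with Si2AK. Of 30 interferon response genes 3 rose, Oasl1 by 1.11 ± 0.13 among them, and 4 fell, including the antiviral gene Mx1 at -1.46 ± 0.212 (adjusted p of the list = 0.173). In the NRF2 and glutathione list 4 of 31 rose and 3 fell, and the glutathione transferase gene Gsta3, well above background on 2 of 3 Si2AK arrays, was at -2.55 ± 0.419 (adjusted p of the list = 0.881). TGF-beta and YAP targets rose in 4 of 18 cases and fell in 3, with Thbs1 at -0.92 ± 0.146 (adjusted p of the list = 0.881). Adjusted over the list alone, 3, 5 and 4 members of these lists rose and 4, 3 and 3 fell. The lists for mesenchymal transition, cholesterol synthesis and Notch pathway (adjusted p = 0.881, 0.0586 and 0.945) and for markers of fibroblasts, leukocytes, endothelium and melanocytes (adjusted p = 0.421, 0.881, 0.823 and 0.881) did not pass. The cholesterol list (median 0.20) passed with medians of 0.19 with slide as a block, 0.20 with the replicate block, 0.39 on slide 1, 0.20 with only the groups compared, 0.19 with the mean of the probes, 0.21 with normexp correction, 0.20 without a filter, and 0.19, 0.23 and 0.23 without Si2AK replicate 2, SiC replicate 2 and SiC replicate 3, so it stays open. On slide 1 the NRF2 list passed (median 0.24). Against NT the fibroblast markers did (0.68), but not with an estimated correlation (camera adjusted p = 0.227). Camera pointed up for the NRF2, Notch and melanocyte lists, whose medians were 0.029, 0.040 and -0.29 and means -0.016, -0.025 and -0.056.

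In all, 2815 genes were called between Si2AK and SiC, 1817 higher and 998 lower, with 231 and 154 at 2-fold or more. Against NT 1698 were higher and 1637 lower, 310 and 132 of them at 2-fold or more. Slc6a2, a noradrenaline transporter, was among the largest falls (-2.04 ± 0.341). With only Si2AK and SiC in the fit, which leaves 6 arrays and no spread shared with the other groups, 89 genes were called. With slide as a block 3498 genes and 15 lists were called, beside 14 lists over both slides. Within either slide 1 of these 2 groups had a single array, so those fits do not repeat the result independently. Without Si2AK replicate 1 the number of genes was 1759.

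**Figure D4:**
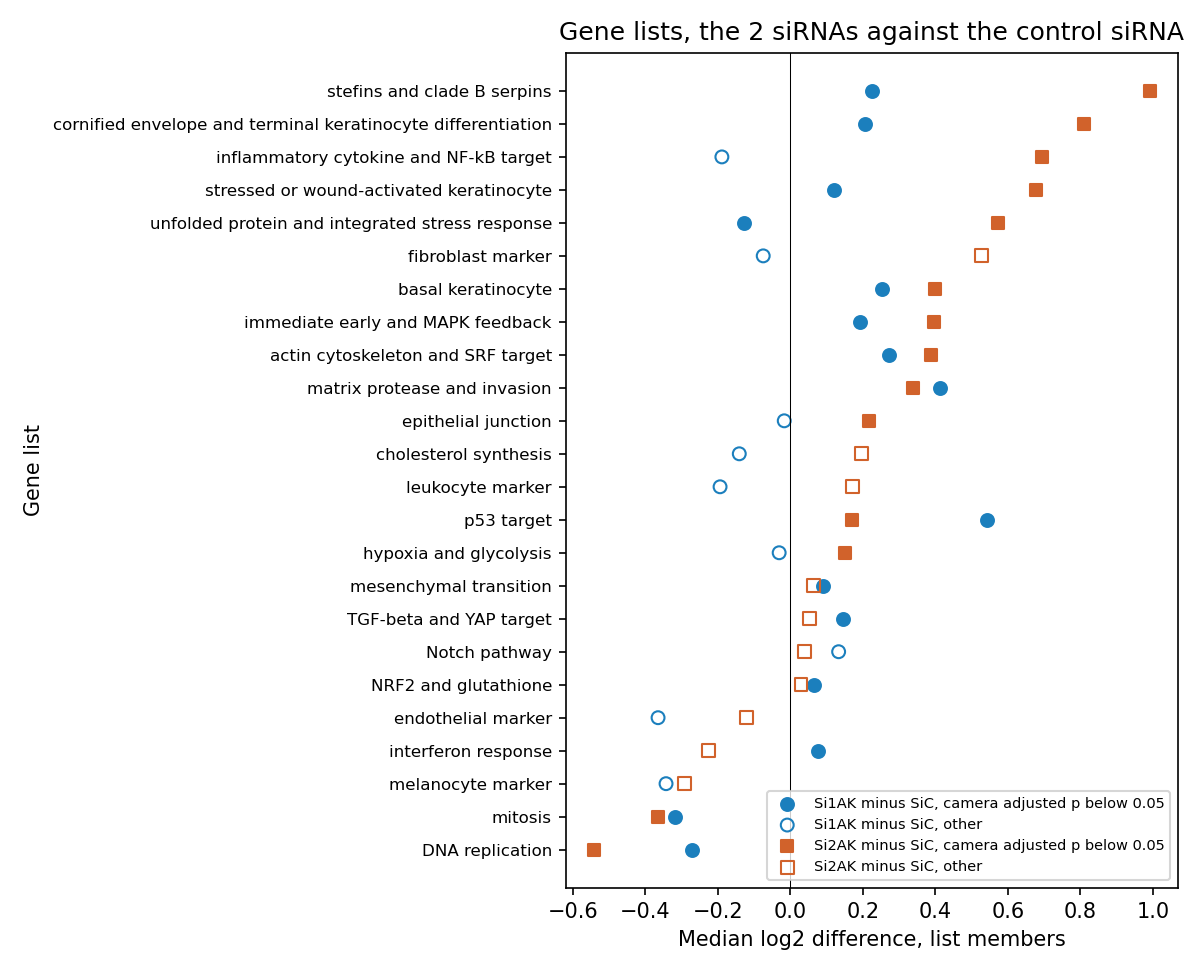
Median log2 difference from SiC over the measured members of each of the 24 gene lists (y axis), for Si1AK and Si2AK (x axis), filled where camera with its preset correlation passed. The inflammatory list stood at 0.69 with Si2AK and -0.19 with Si1AK, and the p53 target list at 0.17 and 0.54.

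The direct test of Si2AK against Si1AK asked where the siRNAs against the same transcript differed. Most members of the unfolded protein and inflammatory lists were called higher with Si2AK. In the unfolded protein and integrated stress response list 23 of 34 genes were higher, 0 lower and 11 not called (23 higher adjusted over the list alone), and 34 differences were positive. Trib3 differed by 2.35 ± 0.271 (adjusted p = 0.000217), Aldh1l2, a mitochondrial folate enzyme, by 2.04 ± 0.295, and Ddit3, the stress transcription factor CHOP, by 1.96 ± 0.293. Inflammatory genes were higher in 18 of 31 cases (18 adjusted over the list alone), with Cxcl2 at 3.50 ± 0.217 (adjusted p = 3.87e-06), Cxcl1 at 2.33 ± 0.238 and the cytokine Il6 at 1.76 ± 0.274. The list medians were 0.73 and 0.95 (adjusted p = 6.69e-16 and 1.59e-11), 0.73 and 1.0 with slide as a block, 0.66 and 0.86 on slide 1, and 0.81 and 1.06 on slide 2. With an estimated correlation their adjusted p = 0.198 and 0.141, and 0 of the 24 lists passed camera that way, where 5 had an unadjusted p under 0.05.

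In 4 keratinocyte lists medians were higher with Si2AK than with Si1AK, and most members of each but the stressed list were not called. Stressed keratinocyte genes were higher in 9 of 19 cases and lower in 2 (12 and 3 adjusted over the list alone), with Ereg at 1.90 ± 0.165 and the keratin Krt16 at 1.42 ± 0.143. Stefins and serpins were higher in 4 of 17 cases and lower in 1 (8 and 1 adjusted over the list alone), with Serpinb1a at 2.75 ± 0.199. Cornified envelope genes were higher in 7 of 31 cases and lower in 3 (9 and 3 adjusted over the list alone), with Sprr2h at 2.02 ± 0.319 and Casp14 at -1.96 ± 0.151. Basal keratinocyte genes were higher in 8 of 21 cases (8 adjusted over the list alone), with Dsg3, well above background on 2 of 4 Si1AK arrays, at 3.97 ± 0.494 and the transcription factor Trp63 at 0.72 ± 0.142. These 4 lists passed (adjusted p = 0.00311, 0.00043, 0.0167 and 0.0143), and with an estimated correlation adjusted p = 0.198, 0.198, 0.342 and 0.421. The basal list did not pass without Si2AK replicate 3 (median 0.13), and neither the basal nor the cornified envelope list passed on slide 1 alone (medians 0.17 and 0.41). On slide 2 alone the medians of the stressed, stefin, cornified envelope and basal lists were 0.83, 0.99, 0.61 and 0.28.

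The p53, DNA replication and interferon lists had lower medians with Si2AK than with Si1AK, and most of their members were not called. Of 32 p53 targets 10 were lower and 3 higher (11 and 5 adjusted over the list alone), with the polymerase Polk at -1.04 ± 0.144 but Plk3 at 1.41 ± 0.134. Of 43 DNA replication genes 12 were lower (18 adjusted over the list alone), with Mcm10 at -0.67 ± 0.112. Interferon response genes were lower in 8 of 30 cases and higher in 3 (10 and 3 adjusted over the list alone), with Oas1a at -1.83 ± 0.112 and Isg15, a ubiquitin-like protein, at 0.94 ± 0.148. TGF-beta and YAP targets were lower in 3 of 18 cases and higher in 2 (5 and 3 adjusted over the list alone), with Thbs1 at -1.63 ± 0.137. These lists passed (adjusted p = 0.00122, 5.36e-12, 0.00122 and 0.0146), and with an estimated correlation adjusted p = 0.198, 0.198, 0.198 and 0.203. The TGF-beta list did not pass without Si2AK replicate 2 (median -0.16) or on slide 2 alone (-0.16). The p53, replication and interferon medians were -0.47, -0.17 and -0.21 on slide 1 and -0.17, -0.35 and -0.23 on slide 2.

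The cholesterol, hypoxia, epithelial junction and immediate early lists had higher medians with Si2AK, and most of their members were not called. Cholesterol synthesis genes were higher in 7 of 26 cases (8 adjusted over the list alone), with the sterol reductase Tm7sf2 at 0.69 ± 0.151. Hypoxia and glycolysis genes were higher in 5 of 34 (6 adjusted over the list alone), with the angiogenic factor Vegfa at 1.03 ± 0.199, and epithelial junction genes in 3 of 20 (3 adjusted over the list alone), with Esrp2 at 0.88 ± 0.08. Immediate early genes were higher in 8 of 33 cases and lower in 3 (11 and 3 adjusted over the list alone), with Atf3 at 2.51 ± 0.355. Adjusted p values of the 4 lists were 0.00241, 0.00853, 0.0355 and 0.0287, and with an estimated correlation adjusted p = 0.421, 0.526, 0.198 and 0.348. The hypoxia median, 0.19, was 0.29 without Si2AK replicate 1. Without Si2AK replicate 3 it was 0.13, without Si2AK replicate 2 the junction median was 0.13, and without Si1AK replicate 3 or Si2AK replicate 1 the immediate early median was 0.22 or 0.26, and these calls were lost. So were those of the immediate early list on slide 1 alone (median 0.21) and with the replicate block (0.26), of the junction list under quantile normalization (0.10) and in the authors' value table (0.10), and of the cholesterol and junction lists on slide 2 alone (medians 0.17 and 0.11), where the only Si2AK array was assumed to vary like the other groups.

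Between the siRNAs the mesenchymal transition, matrix protease, actin, mitosis, NRF2 and Notch lists did not pass (adjusted p = 0.0918, 0.161, 0.104, 0.368, 0.204 and 0.398), nor did the markers of fibroblasts, leukocytes, endothelium and melanocytes (adjusted p = 0.287, 0.883, 0.711 and 0.84). The actin list passed without Si2AK replicate 2 (median 0.15), the matrix protease list without Si2AK replicate 3 (-0.13), and the mitosis list without Si2AK replicate 1 (-0.085) and on slide 2 (-0.13). Without a filter on dim probes the matrix protease, mesenchymal, mitosis and NRF2 lists passed (-0.077, -0.10, -0.008 and 0.052). Camera pointed down for the NRF2, Notch and endothelial lists, whose medians were 0.052, 0.075 and 0.21 and means -0.087, -0.070 and 0.12. In all, 2657 genes differed, 1348 higher and 1309 lower with Si2AK, of which 201 and 246 differed at least 2-fold. The median difference of all genes was 0.097, and -0.041 under quantile normalization. The carbonic anhydrase gene Car6 (3.46 ± 0.478), the peptide hormone gene Adm2 (3.09 ± 0.485), Bhlha15, a transcription factor of secretory cells (3.02 ± 0.426), and Serpinb9e (2.81 ± 0.391) were higher with Si2AK. The aquaporin gene Aqp1 (-2.64 ± 0.141), Ctla2a (-2.59 ± 0.246), Mmrn2 (-2.42 ± 0.107), Spn (-2.36 ± 0.175), the carboxylesterase gene Ces2e (-2.36 ± 0.147) and Gsta3 (-3.29 ± 0.392) were lower. Fgf21, a stress-induced hormone gene, the neuropeptide gene Tac1 and Cds1 were below the background mark with Si1AK and at least 14.6-fold, 9.76-fold and 3.37-fold higher with Si2AK. Ces2b and Boc were below it with Si2AK and at least 1.55-fold and 3.26-fold higher with Si1AK. With slide as a block 3303 genes and 14 lists differed, on slide 1 alone 362 and 11, and on slide 2 alone 391 and 12, beside 14 lists over both slides. Without Si2AK replicate 2 the number of genes was 1748.

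SiC against NT asked what transfection with the control siRNA changed. Inflammatory cytokine genes were higher with SiC as a list, with 28 of 31 differences positive, and so were interferon response genes, with 24 of 30 positive. No member was called over all genes, and 3 and 2 rose adjusted over the list alone. Their medians were 0.37 and 0.34 (adjusted p = 2.53e-10 and 2.18e-07, and adjusted p = 0.086 and 0.086 with an estimated correlation). These medians were 0.38 and 0.34 with slide as a block, 0.087 and 0.60 on slide 1, where the inflammatory list did not pass, and 0.40 and 0.14 on slide 2. Without SiC replicate 1 the interferon median was 0.12, and this list still passed. Over all genes limma called 0, with 1583 at an unadjusted p under 0.05 where 1066 would be expected by chance, and a smallest adjusted p of 0.053. With slide as a block 2 genes and 11 lists were called, on slide 1 alone 0 (7314 at an unadjusted p under 0.05) and 11, and on slide 2 alone 1 and 3, beside 10 lists over both slides. Without SiC replicate 3 the number of genes was 9, and without SiC replicate 1 the number of lists was 4.

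The other 8 lists that passed were fibroblast markers, higher in SiC, and basal keratinocyte, immediate early, mitosis, DNA replication, cholesterol synthesis, hypoxia and glycolysis, and NRF2 and glutathione genes, lower in SiC. Adjusted over the list alone, 1 immediate early gene fell, and limma called 0 members in the direction of their list in the other 7. The fibroblast markers had a median of 0.36 (adjusted p = 0.0126, and adjusted p = 0.388 with an estimated correlation). The lower lists had medians of -0.19, -0.19, -0.10, -0.14, -0.18, -0.17 and -0.15 (adjusted p = 0.00158, 0.00235, 0.0106, 2.57e-06, 6.21e-05, 0.00182 and 0.00158). With an estimated correlation their adjusted p = 0.388, 0.388, 0.524, 0.388, 0.388, 0.562 and 0.407. All 8 calls were lost without SiC replicate 1, the array with the most raised signal, and the medians were then -0.10 for the fibroblast markers and -0.12, -0.095, -0.027, -0.030, -0.047, -0.024 and -0.073 for the others. The hypoxia median was -0.28 without SiC replicate 2. The mitosis call was also lost without NT replicate 4 (median -0.094) and with the replicate block (-0.11), and under quantile normalization the mitosis and fibroblast medians were 0.003 and -0.13. On slide 2 alone, which held SiC replicates 2 and 3, none of the 8 passed and the median was 0.19 for the fibroblast markers and -0.077, -0.052, -0.070, -0.054, -0.088, -0.024 and -0.053 for the others. Leukocyte, endothelial and melanocyte markers (adjusted p = 0.49, 0.508 and 0.187) and the cornified envelope, stressed keratinocyte, stefin, epithelial junction, mesenchymal, TGF-beta and YAP, matrix protease, actin, p53, unfolded protein and Notch lists (adjusted p = 0.284, 0.425, 0.571, 0.478, 0.297, 0.314, 0.781, 0.143, 0.194, 0.11 and 0.194) did not pass. The unfolded protein list passed with slide as a block (median -0.14), on slide 1 (-0.40) and without SiC replicate 1, 2 or 3 (0.016, -0.19 or -0.18), and the matrix protease list on slides 1 and 2 (-0.44 and 0.067) and without SiC replicate 1 (0.021), with medians of both signs. Under quantile normalization the cornified envelope and Notch lists passed (-0.27 and -0.39). Camera pointed down for the epithelial junction and matrix protease lists, whose medians were 0.001 and -0.056 and means 0.089 and 0.042.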

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

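The tests of a uniform background, of RNA from other cells, of a single response of differing strength, of Si2AK replicate 2 and of a rise in the SiC arrays were chosen only after the results were seen. The test of probe GC content and the counts over other splits of the arrays were fixed earlier.

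Named genes had values in NT and Si1AK that could be searched for an array far from the other 3 of its group. By Dixon's criterion on the gap to the nearest array, divided by the range of the group, 1 array stood apart in 17 of 356 groups (4.78%), and chance gives about 1 in 20. In log2 signal relative to the 75th percentile, with the range of the other 3 arrays in parentheses, Si1AK replicate 3 stood apart for Csf2 at -0.44 (-0.070 to 0.000), the keratin Krt6b at 1.98 (2.44 to 2.48), Lce3a at -4.16 (-3.03 to -2.92), the malic enzyme gene Me1 at 3.68 (3.81 to 3.82) and the Notch glycosylation gene Rfng at 3.84 (4.0 to 4.03). Si1AK replicate 2 did so for Cbr3 at 2.21 (1.97 to 1.99) and the Notch coactivator Maml1 at 3.06 (2.80 to 2.83), replicate 4 for Cnn2 at 5.01 (5.16 to 5.18) and the transcription factor Snai2 at 3.83 (3.43 to 3.49), and replicate 1 for Mx1 at -2.61 (-2.31 to -2.30). In NT the values were 3.35 (3.51 to 3.54) for Me1 and 2.99 (2.68 to 2.70) for Plk3 on replicate 4, 2.32 (2.15 to 2.18) for Oasl1, -0.90 (-0.64 to -0.60) for Polk and -3.06 (-5.75 to -5.43) for Zfp607b on replicate 2, 4.52 (4.26 to 4.29) for the hypoxia gene Ndrg1 on replicate 1, and 0.82 (1.29 to 1.33) for Plau on replicate 3.

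The siRNAs differed from each other in 2657 genes and 14 gene lists, and 72 genes were called in opposite directions against SiC. Among named genes called both ways, the tested difference of Si2AK minus Si1AK was -2.64 for Aqp1, -2.59 for Ctla2a, -2.42 for Mmrn2, -2.36 for Ces2e, -2.36 for Spn, -1.83 for Oas1a, -1.63 for Thbs1 and -1.05 for the glutathione transferase gene Gstm1. It was 2.75 for Serpinb1a, 2.67 for Tor2a, 1.31 for the cytokine gene Il1b and 1.17 for the serine synthesis gene Psph. Against SiC some of these calls were lost with single arrays left out. With Si1AK, Il1b lost its call without Si1AK replicate 1, 2 or 3 or SiC replicate 1 or 3 (-0.49, -0.49, -0.52, -0.47 or -0.47) and was at 0.49 under quantile normalization, so its opposite direction is not settled. Psph lost its call without Si1AK replicate 1, 2 or 3 or SiC replicate 2 or 3 (-0.39, -0.44, -0.37, -0.37 or -0.38), Serpinb1a without Si1AK replicate 1 or SiC replicate 2 or 3 (-0.93, -0.91 or -0.84), and Gstm1 without Si1AK replicate 2 (0.55). With Si2AK, Ctla2a lost its call without Si2AK replicate 3 or SiC replicate 1 (-0.80 or -0.82). Such losses against SiC were not tested for Ces2e and Spn, nor with Si2AK for Oas1a, Gstm1, Tor2a, Il1b and Psph.

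SiC replicate 1 and Si2AK replicate 2 had raised signal on dim probes. A uniform background over the array is argued against, since dim probes rose by 2.73 times the rise of the negative control spots on SiC replicate 1 and by 3.43 times on Si2AK replicate 2. RNA from other cells or a few abundant transcripts stays open: 74.9% and 57.5% of the probes that were dim on the other arrays were well above background, but the raised share over all probes already implies about 76.7% and 62.6%, so this test decides nothing. Non-specific signal that depends on GC content stays open: rho between GC content and the log2 rise across probes was 0.407 and 0.31, above a bound of 0.3 set beforehand but only just so on Si2AK replicate 2, and probes are not independent replicates. No biological explanation was tested, and labelling and washing were not recorded.

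The opposite directions of 72 genes were weighed next. A single response that differs only in strength between the siRNAs is argued against. With no shared arrays 17.4% of the genes called with both went opposite ways (99 of 570, exact 95% interval 14.3 to 20.7, with genes taken as independent). Si1AK was set against NT there and Si2AK against SiC, so a difference between SiC and NT can add to this share. With the same baseline for both siRNAs the share was 17.2% against SiC (interval 13.7 to 21.1) and 11% against NT (8.93 to 13.4). The raised signal of Si2AK replicate 2 is argued against as the whole cause of the difference between the siRNAs, since 1748 genes differed without it. Unequal depletion of AK144841 alone would give a response of differing strength, if a gene's direction is the same at every level of depletion. The shares of genes going opposite ways then argue against it as the whole cause of the opposite directions. It may add to differences in size, and the level of AK144841 was not analysed here. Effects of either siRNA on transcripts other than AK144841 stay open and were not tested.

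Of the genes called with both siRNAs, 92 were lower than with SiC. A rise in the SiC arrays is argued against as the whole cause: over these genes the median difference from NT was -0.62 (quartiles -0.73 and -0.47), beside -0.67 from SiC. For 20 of them SiC was above NT at an unadjusted limma p under 0.05, so a rise with SiC stays open for single genes such as Scai. An effect that any targeting siRNA has and SiC lacks was not tested.

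Arrays were also split into other groups of the same sizes. For Si1AK with SiC, 1 of 35 splits, the real one, gave as many genes (941, highest other 0 in limma) and 1 as many lists (15, highest other 14). For Si2AK with Si1AK it was 1 of 35 for genes (2657, highest other 1) and 1 for lists (14, highest other 13). The splits moved arrays between slides, and arrays of the same slide correlated on average, so slide was not held fixed. If arrays can be exchanged across slides, chance is argued against for the genes called in these comparisons. For the lists chance is not excluded, since wrong splits came within 1 list of the real number. Splits that put 2 Si1AK arrays together with 2 SiC arrays called 0 genes but passed from 0 to 10 lists. Camera p-values with the preset correlation are therefore likely too small for these arrays, by an amount that was not measured. Passing with that preset alone is weak evidence for any single list. For Si2AK with SiC the 10 splits are too few for a share under 0.05 (1 split with as many genes, 2815 and highest other 70; 2 with as many lists, 14 and highest other 14). For SiC with NT, 3 of 35 splits gave as many lists (10, highest other 11), so chance cannot be excluded for the lists. Its 0 genes called by limma cannot be tested this way, since all 35 splits reach that number (highest other 6; 1583 at an unadjusted p under 0.05).

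For genes shared by both siRNAs, 2 of 100 drawn splits gave as many, the real one with 347 included. The splits mixed SiC, Si1AK and Si2AK arrays, so they ask whether these groups differ at all. They cannot tell whether the siRNAs share a response. The other split that gave as many had 1066 genes and put the 3 Si2AK arrays in place of the control. This points to a structure of the samples, the distance of Si2AK from the other groups. The next highest gave 27.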

How the results depend on the processing

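The alternatives that left out both arrays with raised signal, or used bright genes only, were chosen after seeing the data, and the others before. Under normexp background correction, quantile normalization, the authors' value table, the stricter filter, the mean of the probes of a gene, the intensity trend and the replicate block, the numbers of genes called with Si1AK, with Si2AK, between the siRNAs and with both stayed within 1.5 times of the values given.

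Without a filter on dim probes more genes were tested, and the numbers of genes called were 400 with Si1AK, 1526 with Si2AK, 1586 between the siRNAs and 116 with both. With only the groups compared in the fit, which leaves fewer arrays, they were 251 with Si1AK, 89 with Si2AK and 19 with both. That fit also shares no spread with the other groups. The mean correlation of an array with its own group was 0.995 in Si1AK, 0.974 to 0.985 in Si2AK and 0.9565 to 0.978 in SiC. How much each of these lowered the counts was not tested. On slide 1 alone, with fewer arrays, they were 0 with Si1AK (limma; 8363 at an unadjusted p under 0.05), 398 with Si2AK, 362 between the siRNAs and 0 with both, and on slide 2 34, 181, 391 and 17. Slide 1 held only 1 SiC array and slide 2 only 1 Si2AK array, so slide counts that use them rest on 1 array of that group. With NT as the control Si1AK gave 1507 genes and both siRNAs 702. Genes with both numbered 536 with slide as a block, 535 among bright genes and 50 at 2-fold or more, a stricter rule. For the other shifts the cause was not tested.

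For SiC with NT, where limma called 0 genes (1583 at an unadjusted p under 0.05), 5 were called with both raised arrays left out, 1 under quantile normalization, 2 with slide as a block and 1 on slide 2. Its number of lists, 10, became 4 with both raised arrays left out, 5 with bright genes only, 5 under quantile normalization, 4 in the authors' table, 3 on slide 2, 2 with fry and 19 without a filter. With an estimated correlation camera called 0 lists for SiC with NT (2 at an unadjusted p under 0.05), 2 with Si1AK, 6 with Si2AK and 0 between the siRNAs (5 at an unadjusted p under 0.05), where the correlation of members widens the variance it assumes. On slide 1 alone 8 lists were called with Si1AK. Otherwise the cause was not tested.

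Leaving out each array in turn gave 427 to 762 genes with Si1AK, 1759 to 2706 with Si2AK, 0 to 9 for SiC with NT, 1748 to 2214 between the siRNAs and 153 to 318 with both, and 12 to 16, 12 to 15, 4 to 11 and 13 to 14 lists for these comparisons in that order. The number was more than 1.5 times lower with Si1AK without Si1AK replicate 1 (460), Si1AK replicate 2 (427) or SiC replicate 2 (627), with Si2AK without Si2AK replicate 1 (1759), and between the siRNAs without Si2AK replicate 2 (1748). For genes with both it was so without Si1AK replicate 1 (153), Si1AK replicate 2 (156), Si2AK replicate 1 (197) or SiC replicate 2 (220). Of 311 named gene results, 219 kept their call with each array left out, and 29 under every alternative run.

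Results that changed sign while called in either fit were few, and the cause was not tested. Under quantile normalization the differences of Si1AK from SiC were 0.49 for Il1b and 0.044 for Itpka, both of which fell in the fit reported. Slc7a3, Soat2 and Maats1, which had fallen too and were chosen after their values were seen, were at 0.55, 0.54 and 0.60. In the authors' table Il1b, Slc7a3, Soat2 and Maats1 were at 0.21, 0.12, 0.20 and 0.098. Without a filter, where a brighter probe can stand for a gene, Sybu was at -1.30 with Si2AK against SiC and Nfatc2 at 0.94 between the siRNAs. For Si1AK the NRF2 median was -0.081 on slide 2 and the unfolded protein median 0.088 on slide 1, and with single arrays left out the hypoxia median ran from -0.20 (without SiC replicate 1) to 0.063. For SiC with NT the hypoxia median was -0.024 on slide 2 and -0.024 with both raised arrays left out, where camera pointed up, and the mitosis median 0.003 under quantile normalization and 0.003 in the authors' table. Its matrix protease median was 0.021 with both raised arrays left out, 0.067 on slide 2 and from -0.17 to 0.021 with single arrays left out, and its unfolded protein median 0.016 and from -0.19 to 0.016. Signal over background limits dim genes most, since between 52.7% and 60.1% of probes were well above background on the 12 arrays without raised signal.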

Other observations

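The genes named in the next paragraph, and S100a16, were chosen after their values were seen, and no test in this part was chosen only after its result was seen.

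Some genes were called in opposite directions with the siRNAs. With Si1AK and Si2AK against SiC, the differences were 1.26 and -1.16 for Mmrn2, a vascular matrix glycoprotein, 0.97 and -1.67 for the water channel gene Aqp1, 0.97 and -1.19 for the acyltransferase gene Mogat2, 1.15 and -1.03 for the carboxylesterase gene Ces2c and 0.91 and -0.90 for Slc7a4, of a family of amino acid transporters. They were -1.41 and 1.18 for the alanine transaminase gene Gpt2 and -0.97 and 0.74 for the thioesterase gene Them4. Against NT the differences were -1.40 and 1.19 for Gpt2, -1.11 and 0.59 for Them4 and 1.04 and -1.60 for Aqp1.

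A joint rise of the epidermal differentiation complex, a cluster of skin barrier genes on chromosome 3 (90315191 to 93368496 of mm9), was a hypothesis set down before its test. It was not among the tests fixed before the data were examined. It was worded for genes called higher with both siRNAs, so those calls may have been seen first. Of 67 genes tested there 9 were higher with both siRNAs (13.4%), beside 246 of 21076 elsewhere (1.17%; 1-sided Fisher's exact p = 1.09e-07). Without the Lce1 genes, whose probes may bind each other's transcripts, 3 of 56 were higher (1-sided Fisher's exact p = 0.0283), namely Crct1, S100a7a and S100a16. The call of S100a16 with Si1AK was lost without Si1AK replicate 1, 2 or 4 or without any SiC array, with differences between 0.31 and 0.42 over single arrays left out. Neighbouring genes are not independent, and the second p rests on 3 genes. The first p counts Lce1 genes that were already among the largest shared rises, so it is no independent support.

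Replicate numbers did not pair the arrays. Of 19 pairs of arrays with the same number in different groups, 12 had a correlation across genes above 0.1 after group means were removed (lowest -0.693, genes not being independent replicates), and 5 of 14 arrays correlated best with their own number. Arrays of the same slide had a mean correlation of 0.235, and arrays of different slides of -0.215. The raised arrays SiC replicate 1 and Si2AK replicate 2 share slide 1 and correlated at 0.874. On that slide too, SiC replicate 1 and Si2AK replicate 1 were at -0.67. These means therefore do not separate slide from raised signal.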
